A study of Mus musculus with 6 samples.

How the data were processed

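The study profiled long non-coding RNA (lncRNA) in mouse pancreatic islets, the endocrine cell clusters that hold the insulin-secreting beta cells. Per the labels, total RNA from islets of C57BL/6 mice was made into Illumina TruSeq libraries after 8 weeks on normal chow (NCD, 3 libraries) or a high-fat diet (HFD, 3 libraries). The series title also names db/db mice, which were not analysed here.

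The deposited file was 1 table of 3093 transcripts with a transcript identifier, a locus identifier, a genomic interval and 2 columns of FPKM (fragment counts scaled to the transcript length and to the total of mapped fragments), 1 per diet group, per the file headers. The 2 columns were used as the authors' value for each group. They carry no value per library, so no standard deviation, replicate count or test between diets could be attached to any value below. How the authors combined the 3 libraries of a group, and the aligner, assembler and quantifier they used, are not given in the sources used here. The submitters' processing notes name the genome builds GRCm38 and mm10. Every deposited transcript had an FPKM of at least 0.410 in 1 of the groups. The file gives no strand and no exon structure.

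Transcripts were placed against the GENCODE M21 annotation, which is on GRCm38. Of the 3093 intervals, 4 had the same start and end as an annotated transcript. An interval touching any annotated exon was called exonic, an interval lying in a gene without touching an exon was called intronic, and the others were split at 5 kb from the nearest gene. A transcript was named after the gene covering most of its interval, so a gene name below says where a transcript lies, not that the gene itself was measured. Without strand, a transcript in a gene cannot be told from that gene's own unspliced or alternative RNA.

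The ratio of diets was log2 of (HFD FPKM + 0.1) over (NCD FPKM + 0.1), which understates the change of low transcripts. The planned minimum of 0.1 FPKM in either group removed 0 transcripts. A difference was described by size, as at least 2-fold. The model across libraries, the set tests, the comparison of library totals, the replicate block and the left-out libraries fixed before the data were examined could not be run on 1 value per group. The size rule replaced them after the file was seen, and so did the ranking of named transcripts. These were the 10 highest and 10 lowest log2 ratios among transcripts above 0 in both groups, at least 400 bases long and lying in a named gene. Members of the fixed lists were named as planned, the 2 with the highest level in each list of at least 3 transcripts. Genes holding several transcripts, the members of lists with fewer than 3 transcripts and the Mir99ahg transcripts were chosen after their values were seen.

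The 17 fixed gene lists covered well-studied lncRNAs, imprinted genes, snoRNA and microRNA hosts, islet-linked lncRNAs, beta cell and other endocrine genes, dedifferentiation, cell cycle, stress, lipid metabolism, 5 groups of other pancreatic cell types and sex-linked genes. The result of 1 of these lists is not reported here. For a list or class, the median log2 ratio was set among 10000 random lists of the same size, drawn from 20 bins of mean level. This percentile describes these 2 columns and is not a p-value. In 100 simulated lists of 5 of the 3093 transcripts, a shift of 1 log2 unit put the list above the middle 95% in 47%. For lists of 10 it did so in 84%, while lists of 10 without a shift lay above in 1% and below in 4%. The percentile of a list of 3 to 5 transcripts can therefore miss a shift of that size. Intervals on medians are 95% bootstrap intervals over transcripts (2000 draws), which do not cover variation between mice.

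The depth was looked for in the low values. With a total and a fragment length fitted to a random part of the transcripts of 300 to 700 bases, values below 8 fragments in the remaining transcripts were compared with whole fragments. Within 0.15 of a fragment, 51 of 66 NCD values (77.3%) and 119 of 129 HFD values (92.2%) were whole, where 30% would be by chance. Fitted to all transcripts of that length, the totals (in units of 1e6 fragments) were 63.5 for NCD and 76.8 for HFD, with a mean fragment length of 290 and 282 bases. The NCD total was 59.0 when fitted to the random part, so it is the less certain of the pair. On simulated data with a true total of 70, the fit returned 69.4 and 69.7 for a single pool of fragments, but 25.1 and 196 for a mean of 3 separately scaled libraries of unequal size. The totals, estimated fragments and counting intervals therefore hold only if each column was counted from 1 pool. One fragment of a 400-base transcript was worth 0.142 FPKM in NCD and 0.109 in HFD. Estimated fragments are given only for intervals of 400 to 1000 bases and assume an unspliced transcript. Their intervals are on the log2 ratio of fragments scaled by the totals, without the 0.1 that the printed log2 ratios and their median include. They come from the exact (Clopper-Pearson) binomial and cover counting error only, since PCR copies are not independent molecules.

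The alternatives tried were pseudocounts of 0.01 and 1, median centring, quantile normalization, a minimum of 0.5 FPKM and summing rows to the locus. Added after seeing the data were a minimum span of 400 bases, leaving out transcripts listed at 0, a 4-fold rule, and random lists for the classes matched on 5 bins of level and on 5 classes of span. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.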

Results

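The table held 3093 lncRNA transcripts from 3042 loci, each with 1 FPKM for chow-fed (NCD) and 1 for high-fat-fed (HFD) mouse islets. There were no values per library, so none of the differences below has a replicate check. Intervals ran from 200 to 662110 bases with a median of 747. The summed FPKM was 15448 in NCD and 17702 in HFD, while the median transcript was at 2.53 in NCD and 1.42 in HFD. The sums differ by less than a single 258-base transcript does, at 1450 FPKM in NCD and 5721 in HFD. The higher HFD sum therefore does not describe most transcripts. Among the 1144 transcripts of 400 to 1000 bases, the median was estimated at 48.6 fragments in NCD and 29.4 in HFD, from totals inferred from the steps in the low values.

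Most of these transcripts lay inside known genes. Of the 3093, 2600 (84.1%) overlapped an annotated gene. In 2054 cases the interval lay wholly in an intron, in 353 it touched an exon of a protein-coding gene, and in 193 it touched exons of non-coding genes or pseudogenes only. A further 270 lay within 5 kb of a gene and 223 lay 5 kb or more away.

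The first question was how the islet lncRNA profile differed between the diets. Most transcripts were lower on the high-fat diet: 2475 had a lower value in HFD and 618 a higher one, a share of higher ones with a Wilson 95% interval of 18.6 to 21.4%. That interval treats transcripts as independent, which those of a shared gene may not be, and does not cover variation between mice. Transcripts in the phosphatase gene Ptprd, in Agbl4 and in Nav3 were far lower in HFD, with medians of -2.64, -1.65 and -2.33 on the log2 scale. Those in the phosphoinositide phosphatase gene Inpp4b were mostly higher, with a median of 0.63, and the imprinted lncRNA Rian was at 47.1 FPKM in NCD and 51.9 in HFD. The median log2 ratio of all transcripts was -0.82 (bootstrap interval -0.87 to -0.78), a ratio of 0.567. By size, 1297 transcripts were at least 2-fold lower in HFD and 194 at least 2-fold higher, including 80 listed at 0 in HFD and 49 listed at 0 in NCD. Relative to the median of all transcripts, the split was 464 lower and 493 higher. The share of lower transcripts among those passing the size rule was thus 87.0% as deposited and 48.5% after centring, and each value below should be read against the table's median of -0.82.

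**Figure D1:**
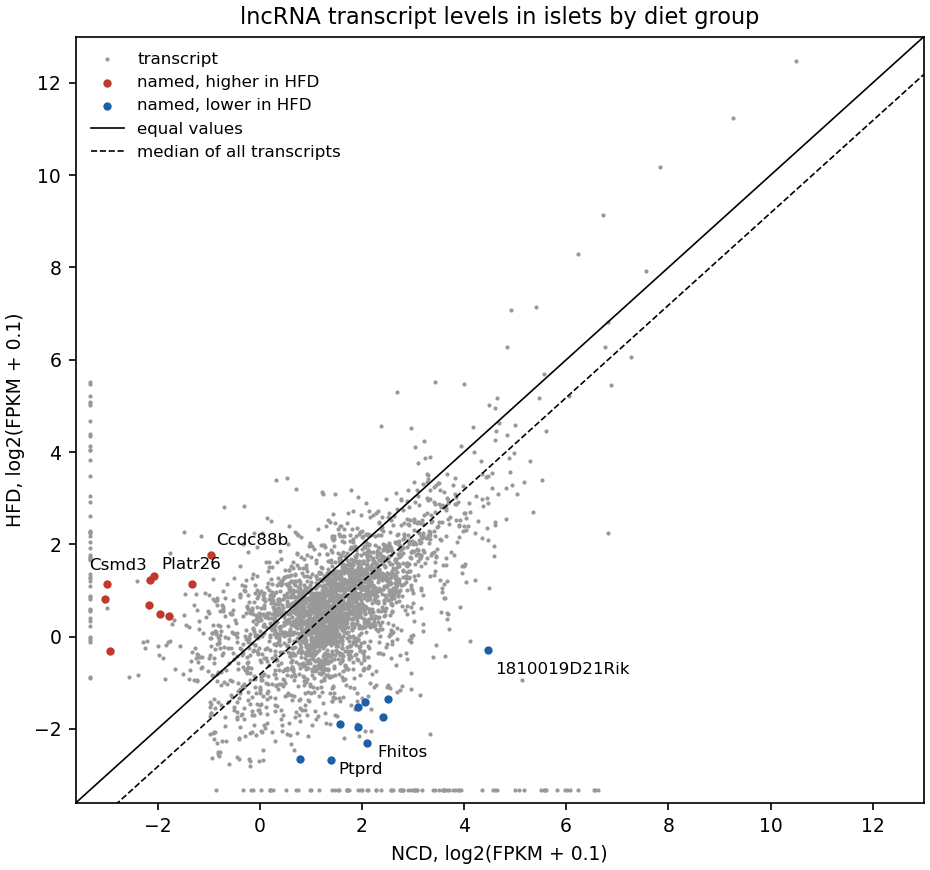
Each grey point is 1 of the 3093 transcripts, placed by log2(FPKM + 0.1) in NCD (x axis) and in HFD (y axis), with the solid line at equal values and the dashed line at the median log2 ratio of -0.82. Red and blue points are the 10 named transcripts with the highest and the 10 with the lowest ratio, and the rows of points along the left and lower edges are transcripts listed at 0 in 1 group.

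The size of the difference depended on where a transcript lay. Intronic transcripts had the lowest median log2 ratio, -0.98 (interval -1.02 to -0.94). Of these 2054, 1003 were at least 2-fold lower in HFD against 91 at least 2-fold higher. Transcripts over coding exons had a median of -0.41 (-0.46 to -0.32) and those over non-coding exons -0.44 (-0.57 to -0.25). Outside genes the median was -0.47 (-0.68 to -0.30) within 5 kb and -0.30 (-0.48 to -0.12) farther away. After median centring the intronic median is -0.16 and those of the other 4 positions lie above 0. Relative to the coding-exon transcripts, the intronic median differed by -0.57 (-0.67 to -0.50). Against the transcripts farthest from genes the difference was -0.68 (-0.86 to -0.49). Among transcripts of at least 400 and under 1000 bases the coding-exon difference was -0.60 (-0.78 to -0.41), while the difference to transcripts far from genes was -0.42 with an interval of -0.75 to 0.17 that includes 0. In FPKM, intronic transcripts of all spans stood out in NCD, with a median of 2.81 against 1.88 to 2.15 for the other positions. In HFD their median of 1.399 lay within the range of the others, 1.31 to 1.59.

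**Figure D2:**
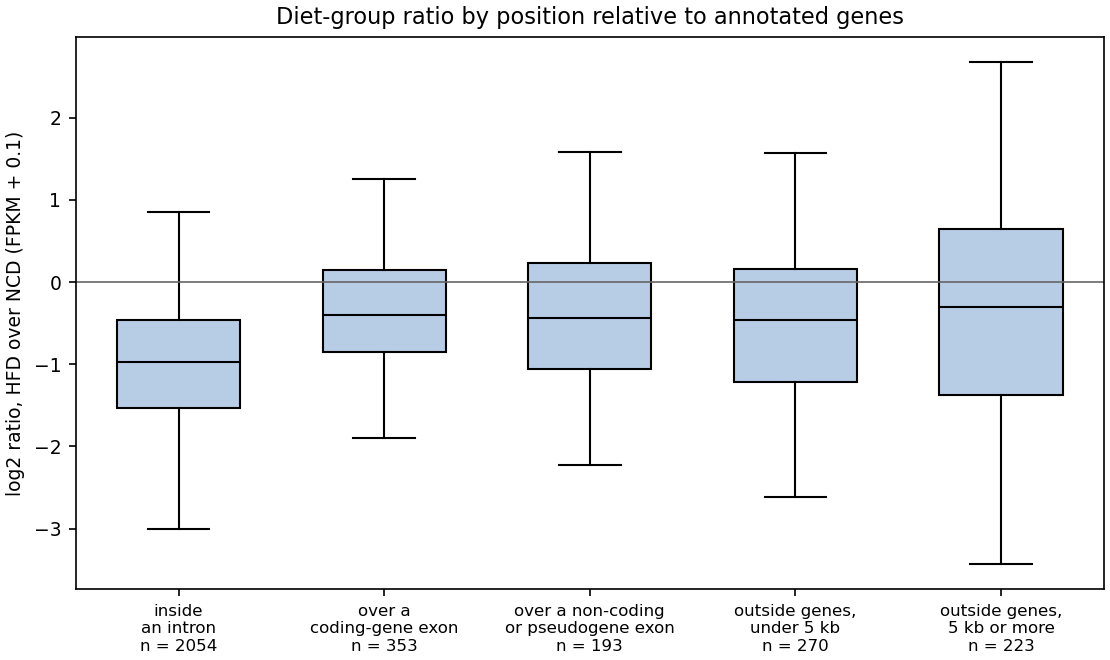
Boxes show the middle of the distribution of the log2 ratio of HFD over NCD (FPKM + 0.1, y axis) from the lower to the upper quartile, with the median as a line and whiskers at the 5th and 95th percentiles, for the 5 positions relative to annotated genes (x axis). The intronic median of -0.98 is the lowest of the 5, and the other 4 lie above the table's median of -0.82.

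By the kind of gene holding the transcript and touched in an exon, transcripts over Gm-numbered gene models had a median of -0.27 (88 transcripts) and those over RIKEN clone genes -0.32 (58 transcripts), each at the 99.98th percentile of random lists matched on level. These classes had long intervals, with median spans of 5975 and 6736 bases, and the median log2 ratio of all transcripts of 5000 bases or more was -0.54. Against random lists matched on span as well, they lay at the 99.9th and 99.5th percentiles. Neither kind of random list was matched on position, and 2054 of the 3093 transcripts drawn from were intronic. A class outside introns can therefore rank high through its position alone. The medians over coding and non-coding exons in general were -0.41 and -0.44, and the interval of the Gm-numbered class was -0.53 to 0.08. These classes went by gene name. The 11 transcripts over genes with names ending in os or as, with or without a number, had a median of -0.12 (98.8th percentile). That rule was meant for antisense or opposite-strand genes. It also took in the snoRNA host gene Gas5 (-2.02) and left out antisense genes with Gm or RIKEN names. The 3 over microRNA genes or hosts with Mir names had a median of -0.13 (90.5th percentile). The 1 over a snoRNA host gene with a Snhg name was at -0.23. The 330 over other named genes had a median of -0.41 and lay above every random list. The intron classes go by the gene holding the transcript, whether or not an exon of another gene is touched, so together they hold more transcripts than the intronic position above. Transcripts in introns of protein-coding genes had a median of -0.99 (1934 transcripts), below every random list, and those in introns of other genes -0.72 (175 transcripts, 90.2th percentile). The 493 transcripts outside genes had a median of -0.42, above every random list. Of these classes, the introns of protein-coding genes alone had a median below that of the table.

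The transcripts with the highest ratio mostly touched exons of their gene (9 of 10). Platr26, an lncRNA named for its link to pluripotent cells, had a transcript at chromosome 2: 71729064 to 71730941 (GRCm38) with 0.138 FPKM in NCD and 2.40 in HFD, a log2 ratio of 3.39. In an intron of Lrrk1, which encodes a leucine-rich repeat kinase, a transcript at chromosome 7: 66336989 to 66337409 was at 0.125 FPKM in NCD and 2.23 in HFD (log2 ratio 3.38). Those values stand for about 1.05 and 24.0 fragments, and the counting interval, taken on fragments without the added 0.1, was 1.69 to 9.67. A 441-base transcript over an exon of Ccdc88b, at chromosome 19: 6858006 to 6858446, was at 0.419 and 3.33 FPKM (log2 ratio 2.73, counting interval 1.62 to 5.03).

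The highest log2 ratios of this group, 4.13 and 3.86, belonged to a pair of isoforms of 1 locus over Csmd3, a large transmembrane protein gene. They lay at chromosome 15: 47800909 to 47858717 and 47800883 to 47858666, at 0.0262 and 0.0220 FPKM in NCD and 2.11 and 1.67 in HFD. The other transcripts of this group lay over Fam83g (log2 ratio 2.86), 5031425E22Rik (2.63), 9230117E06Rik (2.46), Gm49708 (2.46) and 9430065F17Rik (2.22). Values of isoforms that overlap annotated transcripts depend on how the authors' quantification divided the reads, and are uncertain for that reason.

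Of the 2600 transcripts in genes, 1934 lay in introns of protein-coding genes and 175 in introns of other genes. The transcripts with the lowest ratio were likewise mostly short intronic ones (8 of 10), a share that shows no clear excess of introns. The exception in level was a transcript over 1810019D21Rik at chromosome 8: 106135400 to 106138525, a processed transcript gene whose interval also touches a coding exon. It had 21.9 FPKM in NCD and 0.713 in HFD, a log2 ratio of -4.76. Inside Fhitos, the antisense gene of the Fhit tumour suppressor, a transcript at chromosome 14: 10744267 to 10744676 was at 4.20 and 0.102 FPKM (log2 ratio -4.42), about 32.3 fragments against 1.01. In Helq, a DNA helicase gene, the values were 5.25 and 0.201 FPKM (log2 ratio -4.15, chromosome 5: 100782290 to 100782699). In Ptprd, a receptor tyrosine phosphatase gene, they were 2.54 and 0.0567 FPKM (log2 ratio -4.07, chromosome 4: 78096633 to 78097140).

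The remaining transcripts of this group lay in Epb41l4a (log2 ratio -3.89), Asph (-3.85), Macrod2 (-3.48), Map3k21 (-3.47), Gm46348 (-3.45) and Lrmda (-3.45). Counting intervals could be set for 11 of the 20 named transcripts, 2 higher and 9 lower, and all 11 excluded the table's median, which their choice as the extremes of 2029 candidates favours. They cover counting error in these 2 columns and not variation between mice.

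Genes holding several transcripts gave a further view. In 67 genes with at least 5 transcripts each (524 in all), every transcript was lower in HFD in 41 genes, and most were higher in 2 genes. Of the 2054 intronic transcripts, 1777 were lower and 277 higher as deposited. A gene with few transcripts can therefore be lower in all of them without a difference of its own. The random lists used here were drawn across genes, whereas transcripts of the same gene may be parts of a single RNA. The percentiles by gene can therefore look more extreme than they are. Inpp4b, a phosphoinositide phosphatase gene, had 12 of 14 transcripts higher in HFD with a median log2 ratio of 0.63 (99.4th percentile of random lists drawn inside genes). That median is 0.26 with a pseudocount of 1 and 1.45 after median centring. Pdzrn3, a ubiquitin ligase gene, had 7 of 9 higher with a median of 0.36 (99.7th percentile), which is 0.18 with a pseudocount of 1 and 1.18 after centring. Kcnip4, a potassium channel-interacting protein gene, had 5 of 10 higher and a median of -0.09, which changes sign to 0.73 after median centring. Cdkal1, a tRNA-modifying enzyme gene linked to diabetes risk in humans, had 2 of 5 higher and a median of -0.07 (97.6th percentile), which likewise lies above that of the table.

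At the other end, all 7 transcripts in Ptprd (median -2.64, 0.09th percentile), all 11 in Agbl4 (-1.65, 0.28th percentile) and all 6 in Nav3 (-2.33, 1.26th percentile) were lower in HFD. All 5 transcripts in Zbtb16, a zinc-finger transcription factor gene, were lower too, with a median of -2.68 (3.59th percentile). Fhit had 21 of 22 lower (median -1.26) and Immp2l 19 of 21 lower (median -1.12). All 5 in Tcf7l2, a Wnt pathway effector gene, were lower, with a median of -0.97 close to that of all intronic transcripts (39.5th percentile). Of the 67 genes, 4 lay above the middle 95% of random lists and 3 below it. If transcripts of the same gene were independent, 1.68 would be expected on each side.

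**Figure D3:**
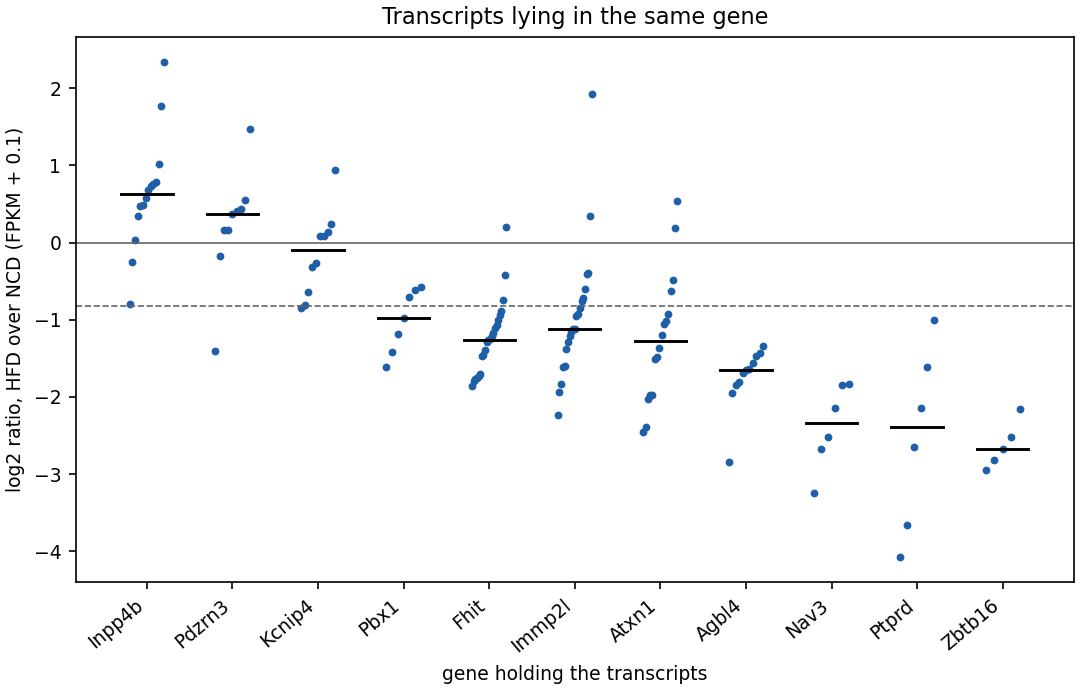
Each point is 1 transcript lying in the gene named on the x axis, placed by its log2 ratio of HFD over NCD (FPKM + 0.1, y axis), with the median as a bar, the solid line at 0 and the dashed line at the table's median of -0.82. Transcripts listed at 0 in 1 group are left out, and the points of Inpp4b lie mostly above 0 while those of Agbl4, Nav3, Ptprd and Zbtb16 all lie below it.

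The fixed lists asked whether transcripts in islet, imprinted or cell type genes differed between the diets, and 19 of their genes held a transcript. In the islet-linked lncRNA list all 4 transcripts were lower in HFD (median -0.70, 60.1th percentile). The transcript in Pax6os1, the opposite-strand partner of Pax6, was at 6.63 FPKM in NCD and 3.57 in HFD (log2 ratio -0.88). The transcript in Nkx2-2os was at 2.95 and 2.02 (-0.53). Of the beta cell genes, which encode the hormones, sensors and transcription factors of insulin secretion, only the transcription factor genes Isl1 and Pax6 held transcripts, and all 3 of these were lower (median -0.49, 74.3th percentile). The Isl1 transcript was at 7.65 and 3.15 FPKM (-1.26) and the higher of the Pax6 pair at 3.10 and 2.17 (-0.49).

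Among imprinted genes, Rian, a non-coding RNA of the Dlk1-Dio3 cluster and host of small RNAs, was among the most abundant entries at 47.1 FPKM in NCD and 51.9 in HFD, a log2 ratio of 0.14. Zrsr1 was at 12.6 and 11.4 FPKM (-0.14), and the list of 3 had a median of -0.14 (86.7th percentile). In the microRNA host list 4 of 11 transcripts were higher and 7 lower (median -0.61, 69.8th percentile). Of these 11, 7 lay in the single gene Mir99ahg, 2 higher (1.42 and 1.33) and 5 lower (down to -1.82), so the list's median and percentile rest largely on that gene. The 2 higher ones had the shortest intervals of the 7, 370 and 296 bases. Their NCD values of 0.798 and 0.593 FPKM stand for few fragments at such spans. The list also held Rian and a Mir670hg transcript at 5.65 and 0.910 FPKM (-2.51). All 4 transcripts of the well-studied lncRNA list were lower (median -1.21, 25.5th percentile), such as those in Dleu2 (-0.90), at 2.53 and 1.31 FPKM, and Jpx (-0.87), at 1.81 and 0.945. Of the 17 lists, 5 had the 3 transcripts needed for a percentile, and these lay within the middle 95% of random lists. That range was wide for such short lists, such as -2.48 to 0.60 for the beta cell list. After median centring or quantile normalization the medians of the islet-linked, beta cell, imprinted and microRNA host lists are above 0, so their direction holds only for the values as deposited.

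The snoRNA host list held 2 transcripts, both lower, in Snhg10 (-0.23) and Gas5 (-2.02). Single transcripts lay in Ddit3 of the stress list (-1.93), the duct list gene Epcam (-2.10) and Jpx of the sex-linked list. In 7 lists 0 transcripts were assigned: other endocrine cells, dedifferentiation, cell cycle, and acinar, endothelial, stromal and immune cells. The levels of these cell types were therefore not measured by this table, and neither Xist nor Tsix held a transcript.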

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

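A minimum span of 400 bases, leaving out transcripts listed at 0, the 4-fold rule and matching random lists on span were chosen after the data were seen. Alternatives were run on the counts by size, the medians by position and list, the 3 genes Inpp4b, Pdzrn3 and Kcnip4, and the 20 named transcripts. No paired analysis was possible because the table gives 1 value per diet group, and for the same reason no library could be left out and no set test, other tool, sample weight or p threshold was run; having no filter removes nothing here. The named transcripts kept their direction in all 80 recomputed values, but their choice as the most extreme ratios left little room for another outcome. A pseudocount cannot change a sign. Their sizes did move. With a pseudocount of 1, 5031425E22Rik went from a log2 ratio of 2.63 to 0.73 and 9430065F17Rik from 2.22 to 0.92, both below the 2-fold rule. The higher Csmd3 isoform went from 4.13 to 1.60, and to 5.87 with a pseudocount of 0.01. Transcripts at least 2-fold higher in HFD numbered 194 as reported, 101 with a pseudocount of 1, 493 after median centring, 499 after quantile normalization, 109 with spans of at least 400 bases, and 90 under a 4-fold rule. Those at least 2-fold lower numbered 1297 as reported and 689, 464, 460 under the first 3 of these and 365 under the 4-fold rule; the fall with a larger pseudocount, fewer transcripts or a stricter rule follows from their construction. The median log2 ratio of all transcripts was -0.87 with a pseudocount of 0.01 and -0.55 with 1; it is 0 after centring by construction and was 0 after quantile normalization. After centring and after quantile normalization, medians turned positive for transcripts 5 kb or more from genes (0.52 and 0.51), nearer to genes (0.35 and 0.36), over non-coding exons (0.38 and 0.38) and over coding exons (0.41 and 0.43), whereas intronic transcripts stayed at -0.16 and -0.14. The list medians that turned positive were those of the beta cell (0.32 and 0.30), imprinted (0.68 and 0.82), islet-linked (0.12 and 0.13) and microRNA host lists (0.21 and 0.21), as did Kcnip4 (0.73 and 0.73). These reversals follow from subtracting the overall shift. The median of the well-studied lncRNA list, -1.21 as reported, stayed negative at -0.39 and -0.40. With a pseudocount of 1 the list medians were -0.57 for well-studied lncRNAs, -0.37 for beta cell genes and -0.32 for microRNA hosts. A minimum of 0.5 FPKM, summing rows to the locus and leaving out transcripts listed at 0 kept the direction of each result they were run on and each count within 1.5 times. Depth limits low values, since a transcript of 400 bases at 0.109 FPKM in HFD stands for 1 fragment.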

Other observations

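The test of the 20 most abundant transcripts of 400 bases or more, the intron test and the test of a few dominant transcripts had their outcomes predicted before their values were seen. The test of the 20 most abundant was then judged by a stricter criterion than the predicted one, as given below. The tests on transcripts far from genes, coding exons, matched spans and fragment steps were chosen afterwards.

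A set of 129 transcripts was listed at 0 in 1 diet group. The 80 listed at 0 in HFD had a median of 7.55 FPKM in NCD, and the 49 listed at 0 in NCD had a median of 3.32 FPKM in HFD. The highest of the first set lay in an intron of Dnah11, an axonemal dynein gene (98.7 FPKM), over an exon of Tmed4 (94.9 FPKM) and in an intron of Rundc3b (93.6 FPKM). The highest of the second lay in an intron of Gm26811 (45.8 FPKM) and near Tab2 (44.3 FPKM). Spans under 300 bases made up 46 of the 80 and 26 of the 49, against 199 (6.43%) of all 3093 transcripts. Such spans are shorter than or close to the mean fragment, which inflates their FPKM. Extrapolating the fit, 1 fragment at 210 bases was worth 1.25 FPKM in NCD and 0.972 in HFD, against 0.142 and 0.109 at 400 bases. The high values of these short intervals therefore do not by themselves show abundant RNA. On chromosome Y, 3 transcripts were above 0 in both groups, the highest at 48.9 FPKM in NCD and 21.9 in HFD, and 1 mitochondrial transcript was at 108 and 77.6 FPKM. With the intronic transcripts of coding genes ordered by host gene length, the 473 in the longest genes had a median log2 ratio of -1.11 and the 473 in the shortest -0.92, with Spearman's rho of -0.07 across 1890 transcripts, which are not independent replicates.

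The lower level of most transcripts in the HFD column has several candidate explanations besides diet, which cannot be separated from the libraries with 1 value per group. Dominance by a few transcripts of this table is argued against, since the 10 with the highest HFD values hold at most 0.338% of all HFD fragments, but dominance by RNAs outside it, such as messenger RNAs, was not tested and stays open. A single scale factor is argued against as the whole cause, because intronic transcripts lay -0.57 log2 units from coding-exon ones (-0.67 to -0.50), although the medians of 4 groups of rising mean level differed by at most 0.19. A lower share of unspliced pre-mRNA in the HFD libraries goes with the intronic median lying -0.68 (-0.86 to -0.49) from that of transcripts far from genes. Those far transcripts had a median of -0.30 (-0.48 to -0.12), which pre-mRNA from inside annotated genes would not lower. Their distance does not exclude unspliced RNA running past annotated ends or from unannotated genes. Without strand and exon structure, the pre-mRNA explanation stays open for them. Less genomic DNA in the HFD libraries cannot be told apart from a lower share of pre-mRNA at matched spans. There the difference between intronic and far transcripts was -0.42 with an interval of -0.75 to 0.17 that leaves both open.

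Some of the most abundant transcripts were much higher in HFD. Of the 20 with the highest mean FPKM, 11 were higher, 7 of them at least 3-fold, such as a 258-base transcript on chromosome 18 at 1450 and 5721 FPKM and one in D130009I18Rik at 618 and 2421, while others were lower, such as the 3 named above as listed at 0 in HFD, and the median log2 ratio of the 20 was 0.08. Of these 20, 15 spanned under 400 bases, and the 20 most abundant transcripts of 400 bases or more had a median log2 ratio of -0.93 (-1.58 to -0.14), with 5 higher. The outcome predicted beforehand if short spans gave the high values was a median below 0, and it was met. Most transcripts of the table lie below 0, so meeting it does not decide the question. A stricter criterion, not part of that prediction, asked for an interval below the median of all transcripts, -0.82. The interval includes that median, so whether short spans gave the high values cannot be told from this. Among the 7 was also a 488-base transcript on chromosome 3 at 229 and 1153 FPKM. An effect of diet on them stays open, and whether these loci share a repeated sequence was not tested, as no genome sequence was used here.

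The FPKM values came in steps, which may say how each column was made. In both columns low values were mostly whole fragments, 77.3% in NCD (exact interval 65.3 to 86.7%) and 92.2% in HFD (86.2 to 96.2%). A simulated mean of 3 separately scaled libraries of unequal size gave 29.4% and 40.5%. A simulated single pool gave 100%, which neither column reached. A mean of libraries of equal size was not simulated and would also come in whole steps, so averaging is not excluded. A candidate explanation is that each column was counted mostly from 1 pool of fragments, either 1 library or the 3 merged. Which of these applies, and any biological explanation, was not tested.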
